A study of Homo sapiens with 10 samples.

How the data were processed

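Splicing was measured in 10 RNA-seq libraries of 293T cells. Per the labels, RBM25 was depleted by CRISPR/Cas9 for 4 days with a control sgRNA beside it, or GFP, RBM25 or RBM25 K77R was stably overexpressed, with 2 libraries in each of the 5 groups. Per the labels' protocols, RNA was enriched with oligo(dT) and copied to cDNA with random hexamers. Per the submitters' processing notes, reads were handled with HISAT2 2.0.3 and SAMtools 0.1.19 on GRCh38. The event caller, its annotation and any minimum of reads are not given in the sources used here. The deposited table holds, for each event and library, the percent spliced in (PSI) made by the authors, as percent values from 0 to 100. It holds no reads, so the depth behind a PSI is unknown, and values such as 0, 50 and 100 with no spread between libraries occur. Columns of the depletion experiment named for Cas9 were read as the control libraries and those named for KO as the RBM25-depleted ones. Some lines of the table were not analysed here.

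The table held 250660 events, of which 229842 contain a junction it marks as unannotated and 20818 only annotated junctions. GENCODE release 29 on GRCh38 contained 28579 of the 30522 distinct junctions of the latter (93.63%), and 31673 of 31681 cassette exons matched an exon of it, so exon numbers, coding status, sequence and intron lengths were taken from it. Gene names came from the table for 173088 events and from GENCODE for 64564, and 13008 had none. Of 40645 Ensembl identifiers in the names, 40536 matched a symbol. After list results and named events had been seen, names joined from distant genes were noticed, and names whose GENCODE locus does not overlap the event were dropped in 8002 events. With the names as given, 756 of 10388 genes had a call and no list passed either (smallest adjusted p 0.24 in place of 0.3192).

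Differences in PSI points were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 10 libraries in 1 fit (5 residual degrees of freedom) and moderated variances with trend and robust options. An event was tested where all 4 compared libraries had a PSI and these were not identical. P-values were adjusted by Benjamini-Hochberg over the events of a comparison, and an event was called at an adjusted p under 0.05 with a difference of at least 10 points. The 4 comparisons were depletion against control, RBM25 and K77R against GFP, and K77R against RBM25. Tested on simulated data for the depletion comparison (108331 events), the fit recovered 66% of 100 events that fell by 20 points and 88% of 100 that fell by 40, with 9 false calls, and in a separate simulation without changes (108347 events) it made 0 calls. Both simulations hold more events than the 75073 tested in the real comparison. They drew normal noise around each event's mean, so they lack values that repeat within a group and differ between groups. Regrouped overexpression libraries gave 192 to 270 calls summed over their comparisons, so the simulated false calls do not bound those in the real values.

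The split of cassette exons was tested with an exact binomial test over genes (the event with the smallest p per gene). The 12 gene lists cover SR proteins, hnRNP proteins, U1 snRNP, U2 snRNP and 3′ splice site recognition, the RNA-binding motif family, apoptosis, DNA repair, cell cycle, chromatin enzymes, kinase signalling, cytoskeleton and ribosomal proteins. Each was compared with 10000 random gene lists matched on tested events per gene. Exon features were compared by permutation with 100000 resamples. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Group means are given ± SD over 2 libraries.

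The groups, the 4 comparisons and their tests, the gene lists, most alternatives and the rule for named genes were fixed from the labels before the values were seen. The study was recognised from its labels at that stage, and its main finding of lower exon inclusion after depletion and a minimum of 10 points were recalled when the tests were chosen, so the direction was not unforeseen. Alternatives and tests added after the values were seen are named in the closing sections and in the text on sensitivity. The rule names RBM25 and BCL2L1 in every comparison. For depletion it takes called events whose libraries do not overlap between groups, 1 per gene by size of the difference: 12 lower and 6 higher cassette exons, 2 in each direction for every other type and up to 4 genes per list. For each overexpression comparison it takes the 6 largest. Some events it selects are not reported here. Alternatives changed the scale, the variance model, the libraries in the fit, the handling of missing and extreme values, the centring, the thresholds and the events counted, and left out each library in turn.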

Results

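The study measured RNA splicing in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen, by sequencing oligo(dT)-enriched RNA. It asked how splicing depends on RBM25, an RNA-binding protein of the RNA-binding motif family that associates with the U1 snRNP, the particle that recognises 5′ splice sites. In the first experiment RBM25 was depleted with CRISPR/Cas9 for 4 days and compared with cells that received a control sgRNA. In the second experiment cells stably overexpressed GFP, RBM25 or RBM25 carrying the K77R substitution. Each of the 5 groups had 2 libraries, 10 in all. The measurement was the percent spliced in (PSI), the share of transcripts of a splicing event that carry the form listed as included. The deposited table held 250660 events of 10 types, and between 154576 and 163465 of them had a PSI in a given library. Over cassette events with a value in all libraries, the libraries of a group correlated at a Pearson r of 0.963 (control), 0.943 (depleted), 0.961 (GFP), 0.963 (RBM25) and 0.959 (K77R), and the median PSI was 100% in every library. The table gives PSI without reads, so the depth behind each value is unknown and no interval for counting error can be attached to it. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

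In the RBM25 gene itself, the inclusion of 1 coding exon was much lower in the depleted cells. Exon 4 of 19 (168 nt, GRCh38 chromosome 14, 73077369 to 73077536) was included at 52.3% ± 3.22 after depletion and at 100% ± 0 in the controls (mean ± SD, n = 2 libraries each). Its PSI fell by 47.7 points (SE 2.45, adjusted p = 0.0025, limma). The single values were 54.55% and 50% in the depleted libraries and 100% in the other 8 libraries. The other 10 RBM25 events tested between these groups did not pass the threshold. PSI carries no information on the amount of RBM25 mRNA, so the extent of depletion is not given here. The guide's target site is not given in the sources used here, so skipping of exon 4 through the edit itself is not excluded.

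Exon inclusion was lower in depleted cells at most of the cassette exons called. Of 16008 cassette exons tested, 545 were included less often and 20 more often in depleted cells (limma, adjusted p under 0.05 and a difference of at least 10 points). Counted once per gene, inclusion was lower in 474 genes and higher in 19 (exact two-sided binomial p = 6.88e-115, where genes are not independent replicates). Logit-transformed PSI gave 320 lower and 25 higher, leaving out a depleted library 1432 and 50 or 1462 and 49, and leaving out a control library 575 and 186 or 540 and 217. Counts from fits without 1 library rest on a lone library assumed to vary like the rest. The median change was −23.6 points among the exons that fell and 17.7 points among those that rose. Exons that fell had a median PSI of 98.5% in the controls and 73.2% in the depleted cells, and 236 of them were included at 100% in both control libraries. Exons above 95% in the controls cannot rise by 10 points, so the equal split that the binomial test assumes does not hold for them. At a control PSI above 20 to 80 inclusion was lower in 39 genes and higher in 9 (exact binomial p = 1.52e-05). By annotation 502 of the 545 were coding exons, 22 were part coding, 13 lay in untranslated regions and 8 in non-coding transcripts. Of the 545 events, 487 involved at least 1 junction that the table marks as unannotated and 58 only annotated junctions.

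The largest falls were in genes of several cellular processes. Exon 7 of 13 of HARS2, the mitochondrial histidyl-tRNA synthetase (99 nt, chromosome 5, 140696103 to 140696201), was included at 12.5% ± 3.54 after depletion and 79.2% ± 5.89 in controls (n = 2 each, adjusted p = 0.00592). Exon 7 of 14 of HDAC1, a histone deacetylase (93 nt, chromosome 1, 32329068 to 32329160), was included at 35.6% ± 0.95 and 92.3% ± 1.89 (n = 2 each), and its PSI fell by 56.7 points (SE 2.88, adjusted p = 0.0025). Exon 10 of 15 of CHEK2, a DNA damage checkpoint kinase (87 nt, chromosome 22, 28696901 to 28696987), fell by 62.5 points (SE 9.21, adjusted p = 0.0265) to 25% ± 6.43. Exon 22 of 43 of FANCD2, a DNA crosslink repair protein (74 nt, chromosome 3, 10064356 to 10064429), fell by 61.6 points (SE 8.6, adjusted p = 0.0222). Exon 7 of 19 of ABCD4, a lysosomal cobalamin transporter (51 nt, chromosome 14, 74295148 to 74295198), went from 100% ± 0 to 31.8% ± 11.65. Exon 2 of 7 of LAMTOR3, a subunit of the lysosomal Ragulator complex (46 nt, chromosome 4, 99893955 to 99894000), fell by 63.9 points, and it is part coding and part untranslated. SLC12A9, ZFYVE27, TRMT2A, SH3GLB2, CHKB and DNAAF5 completed the 12 largest, with differences of −64.6, −61.9, −59.9, −57.5, −56.2 and −55.5 points. CHEK2 did not pass with logit-transformed PSI (adjusted p = 0.349) or in 3 of 4 fits that left out 1 library (adjusted p = 0.0502, 0.0535 and 0.0688), and SLC12A9 and CHKB did not pass with logit-transformed PSI nor FANCD2 without 1 control.

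**Figure D1:**
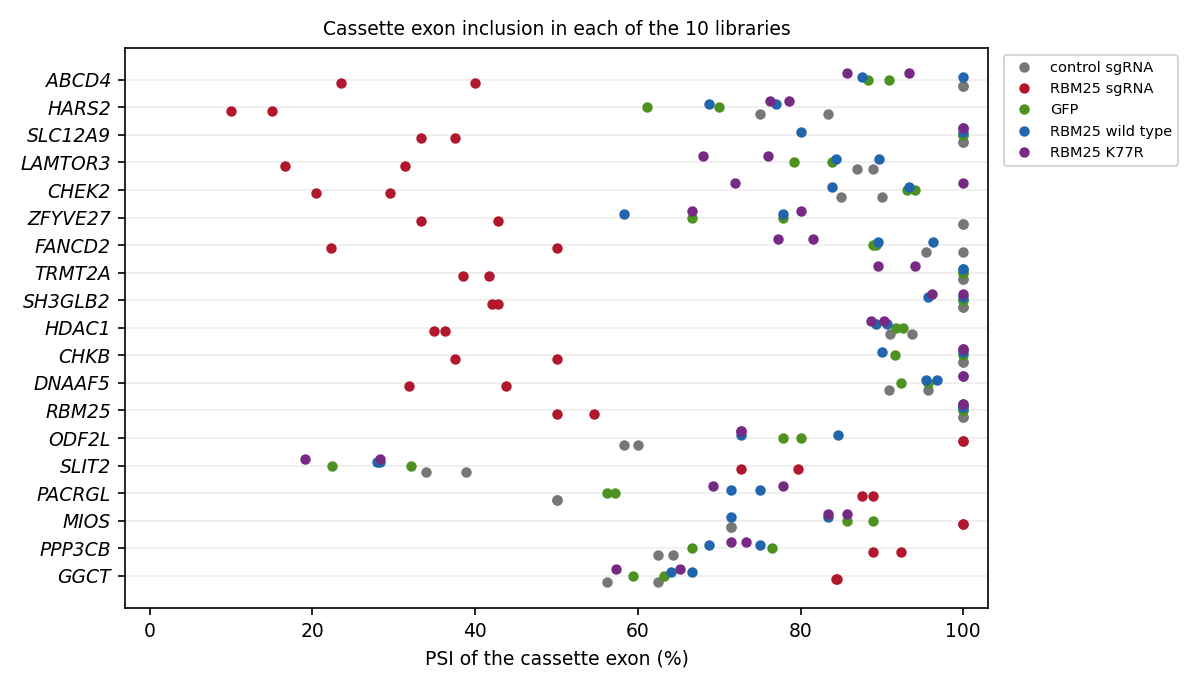
PSI in percent (horizontal axis) of 19 cassette exons (rows, by gene) in each of the 10 libraries, with 1 point per library coloured by group. The RBM25-depleted libraries lie below all others for the 12 exons with the largest falls and for RBM25 exon 4, and above all others for the 6 exons with the largest rises, such as SLIT2.

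Exons with higher inclusion after depletion were few with all libraries. More were called without 1 of the controls, but a lone control is assumed to vary like the rest, so this does not show more rises. The largest rise was in exon 3 of 18 of ODF2L (133 nt, chromosome 1, 86385458 to 86385590), from 59.2% ± 1.18 to 100% ± 0 (n = 2 each, adjusted p = 0.00992). The 12-nt exon 9 of 39 of SLIT2, a secreted axon guidance protein (chromosome 4, 20490803 to 20490814), rose from 36.4% ± 3.46 to 76.2% ± 4.94 (adjusted p = 0.0177). PACRGL rose by 38.2 points, MIOS, a component of the GATOR2 complex, by 28.6, PPP3CB, a catalytic subunit of calcineurin, by 27.2, and GGCT, γ-glutamylcyclotransferase, by 25.1, though GGCT did not pass with logit-transformed PSI nor PPP3CB without 1 control.

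Across all types, 1013 of 75073 events in 752 genes passed, of which 792 were lower and 221 higher, and 8372 had an unadjusted p under 0.05. Coordinated cassette events, in which neighbouring exons are included or skipped together, fell in 100 cases and rose in 3, with SH3GLB2 at 33.8% ± 4.29 after depletion and 100% ± 0 in controls. Alternative acceptors (39 lower, 38 higher) and alternative donors (33 lower, 41 higher) had similar numbers in each direction. The same held for junction-only acceptors (14 and 16) and donors (17 and 16). Competing sites can be listed as separate events that mirror each other, as in FUBP1 and QTRT1 below. A switch then counts in both directions, so these balances are partly set by the listing. First exons were lower in 9 events and higher in 3, and last exons lower in 14 and higher in 7. Mutually exclusive exons were higher in all 5 called events, among them ABI1, an actin regulator, from 0% to 35.8% ± 8.25, and MBNL1, a splicing regulator, from 0% to 50% in both depleted libraries. Their direction depends on which exon of a pair is listed as included, so it cannot be set against that of cassette exons. Among the overexpression libraries MBNL1 had a PSI only in the first K77R library, at 44.44%, near the depleted value. The call count depends on the fit: limma on the 4 libraries of this comparison alone left 0 calls, with 6234 events at an unadjusted p under 0.05. Limma on all 10 libraries with a block for the library number also left 0, with 7774 such events. These 2 fits had 2 and 3 residual degrees of freedom in place of 5. The 1013 calls thus rest on sharing the spread over all 5 groups without a block. Leaving out 1 of the 4 libraries gave more calls, which rest on a lone library in a group. Centring each library on its mean over events with a mean PSI of 5 to 95, tried after the data were seen, turned the split to 739 lower and 4387 higher events (cassette exons 332 and 1477), of which 3843 differed by under 10 points as deposited.

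**Figure D2:**
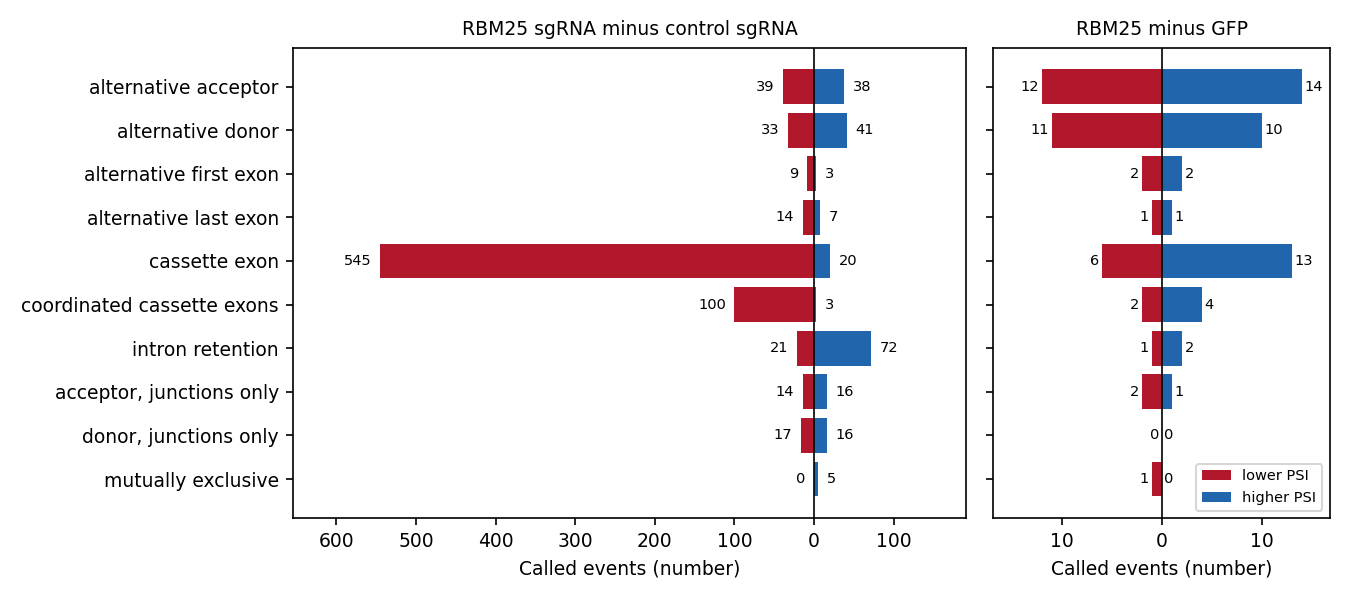
Number of called events (horizontal axis) of each event type (rows), with lower PSI drawn to the left and higher PSI to the right, for depletion (left panel) and RBM25 overexpression against GFP (right panel, other scale). On depletion 545 cassette exons were lower and 20 higher, and with overexpression 6 were lower and 13 higher.

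Cassette exons of intermediate inclusion were lower on average too, in a test added after the data were seen. Over 1165 cassette events with a mean PSI of 20 to 80 in the 6 overexpression libraries, which are not part of the comparison, the mean PSI was 51.2% ± 0.317 in depleted cells and 58.8% ± 0.176 in controls (n = 2 each), a difference of −7.57 points. The exact two-sided permutation p was 1 in 3, the smallest that 2 against 2 libraries allow. Among called cassette exons in this range 54 were lower and 7 higher (88.52% lower). With a control PSI above 20 to 80 the numbers were 43 and 9.

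**Figure D3:**
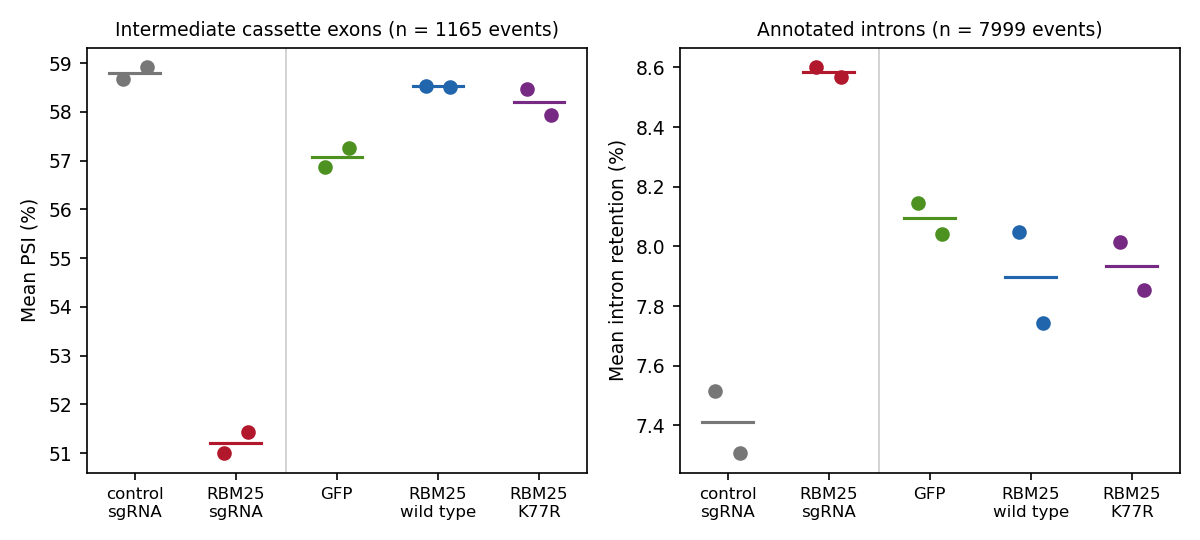
Mean PSI in percent over 1165 cassette events with a mean PSI of 20 to 80 in the overexpression libraries (left) and mean intron retention in percent over 7999 annotated introns (right), with 1 point per library and a line at the group mean. The depleted libraries lie near 51.2% in the left panel and 8.58% in the right panel, where the controls lie near 58.8% and 7.41%.

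Retention of annotated introns was more often higher than lower after depletion. Of the called retention events 72 were higher and 21 lower, with 62 higher and 5 lower among introns with only annotated junctions, and 10 higher and 16 lower among those with an unannotated junction. Retention of the 108-nt HRAS intron at chromosome 11, 532523 to 532630, rose from 17.2% ± 0.22 to 47.7% ± 1.65 (n = 2 each, adjusted p = 0.0114, limma). COQ4, a factor of coenzyme Q synthesis, rose by 64.1 points (SE 10.09, chromosome 9, 128323148 to 128325142), and MAN2C1, a cytosolic mannosidase, rose by 49.9 points (SE 8.34, chromosome 15, 75359989 to 75360089), though neither passed with logit-transformed PSI. In FUBP1, a single-stranded DNA-binding regulator, the listed interval (chromosome 1, 77945643 to 77946529) fell from 73.2% ± 3.98 to 16.4% ± 1.29, and in HMGN1, a nucleosome-binding protein, from 100% ± 0 to 44.4% ± 0. Over 7999 annotated introns the mean retention was 8.58% ± 0.023 in depleted cells and 7.41% ± 0.148 in controls, with 8.09% ± 0.075, 7.9% ± 0.217 and 7.93% ± 0.115 in GFP, RBM25 and K77R cells. Over 8970 listed intervals with an unannotated junction the mean PSI was 88.97% ± 0.042 and 89.16% ± 0.027 in depleted and control cells, and 89.18%, 89.1% and 89.16% in GFP, RBM25 and K77R cells. Unlike annotated introns, such intervals were mostly kept in every group. A lower PSI there, as in FUBP1 and HMGN1, means more use of a junction across the interval.

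Other event types held large single changes. FUBP1 switched between acceptors, with 1 junction falling from 92.7% ± 1.82 to 44.3% ± 0.15 and another rising from 5.66% ± 1.11 to 53.6% ± 0.33. In QTRT1, a subunit of the tRNA-guanine transglycosylase, alternative donor use went from 100% to 0% in both depleted libraries, with the competing donor going from 0% to 100%. NBEAL2 donor use rose from 11.25% ± 1.77 to 80.6% ± 3.92. Use of a last exon of EVL, an actin regulator, fell by 70.8 points (SE 9.01) but did not pass with logit-transformed PSI (adjusted p = 0.186), and a last exon of PMS1, a mismatch repair protein, rose by 33.0 points (SE 4.32). The coordinated exons of BCAT2, a mitochondrial aminotransferase, rose from 20% ± 0 to 70.8% ± 5.89, and those of LRRFIP2 rose by 32.8 points (SE 5.02) but did not pass without 1 control.

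Exons that fell differed in build from exons that were not called. The 545 lower exons had a median length of 94 nt against 111 nt in 15443 exons not called, and 53.58% of them were a multiple of 3 nt long against 44.9%. Their median GC content was 53.8% against 48.6%. They lay between shorter introns, with median lengths of 1093 nt upstream and 873 nt downstream against 1935 and 1738 nt. Permutation tests gave adjusted p-values of 3e-05 for length, GC content and both introns and 0.000144 for the multiple of 3 (12 tests, two-sided, 100000 resamples). The hexamer CGGGCA, known to bind RBM25, was present in 2.75% of lower exons and 2.44% of exons not called (adjusted p = 0.895). The 20 higher exons had a median length of 74 nt (adjusted p = 0.0216), which did not pass against exons matched on control PSI (adjusted p = 0.0944). Exons not called are no unchanged group, since the median difference over all cassette exons tested was −1.875 points. Calling also depends on the spread of PSI between libraries and so on depth, which is unknown and was not matched.

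None of 12 gene lists fixed beforehand held more or fewer genes with a called event than random lists matched on the number of tested events per gene (adjusted p from 0.3192 to 1). Of all 9205 gene entries tested, where an entry is 1 gene or neighbouring genes that share an event, 752 (8.17%) had a called event. Among splicing factors, none of 31 entries of the list of 28 SR proteins and related factors had a call where 4.12 were expected (random-list permutation, raw p = 0.0266, adjusted p = 0.3192). Of 23 entries of the U1 snRNP list 3 had a call, all lower, among them RBM25 itself and TIA1. Exon 5 of 13 of TIA1 fell by 39.6 points (SE 6.11). Of 33 entries of the hnRNP list 2 had a call: exon 2 of 9 of HNRNPD fell from 80.2% ± 0.58 to 55.4% ± 4.72, and a donor of HNRNPA3 rose by 56.6 points. U2AF2 was the only call among 21 entries of the U2 snRNP and 3′ splice site list, where exon 3 of 12 fell by 11.2 points, and RBM33 the only call among 34 entries of the RNA-binding motif list, where exon 2 of 18 fell by 10.4. Adjusted over the list alone, these 5 splicing lists had 0, 3, 1, 0 and 0 entries called in the order SR, U1, hnRNP, U2 and RNA-binding motif.

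In the remaining 7 lists calls were spread over many functions. Random lists matched on tested events held on average 6.43 called entries for DNA repair, 8.07 for cell cycle and 11.68 for chromatin. For apoptosis, kinase signalling and cytoskeleton they held 2.4, 5.88 and 6.15. Of 58 DNA repair entries 10 had a call, with CHEK2 and FANCD2 the largest and exon 7 of 35 of RIF1 falling from 100% ± 0 to 74.0% ± 2.83. Of 78 cell cycle entries 13 had a call: NUMA1, a spindle pole protein, fell by 43.9 points in an untranslated exon, and exon 4 of 5 of CCND3, cyclin D3, fell by 29.2. Of 111 entries of the chromatin enzyme list 11 had a call, all of their 10 called cassette exons being lower, among them HDAC1, HDAC7 (fell by 36.4 points) and SETD5 (fell by 23.6 points). Of 31 apoptosis entries 4 had a call. BAX acceptor use fell by 26.2 points, coordinated exons of BCL2L12 fell by 31.9 points and those of BBC3 fell by 32.5, and a first exon of CFLAR rose by 12.1. Of 56 kinase and growth signalling entries 6 had a call, where exon 33 of 58 of MTOR fell by 19.1 points and exon 36 of 42 of TSC2 fell by 23.7. Of 61 cytoskeleton and trafficking entries 7 had a call, with exon 15 of 29 of SEC31A, a COPII coat subunit, falling from 42.6% ± 1.91 to 10.5% ± 1.13. Of 87 entries of the ribosomal protein list 6 had a call where 11.63 were expected (adjusted p = 0.4112). RPL24 last exon use fell from 97.4% ± 0.54 to 71.4% ± 0.35, and RPLP2 donor use rose from 9.73% ± 0.11 to 34.2% ± 0.8. Adjusted over the list alone, the DNA repair, cell cycle, chromatin, apoptosis, kinase, cytoskeleton and ribosomal lists had 10, 16, 9, 8, 6, 8 and 6 entries called. Among the examples, U2AF2, TIA1, HNRNPD, HNRNPA3, CCND3, HDAC7, SETD5 and BAX did not pass with logit-transformed PSI, and BBC3, TSC2, SEC31A and HDAC7 did not pass without 1 of the libraries.

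BCL2L1, an apoptosis regulator known as a splicing target of RBM25, had 8 events tested on depletion and none passed the threshold. Donor choices at another BCL2L1 acceptor had a test only in the comparisons of K77R cells with GFP or RBM25 cells. The donor choice known to depend on RBM25 was not matched to the tested events. The 8 events on depletion are therefore no negative result for that choice. The largest differences were in competing donors, at −58.3 points (SE 10.53, adjusted p = 0.052, limma) with 0% in both depleted libraries and 58.3% ± 11.79 in controls, and at 45.8 points (SE 19.08, adjusted p = 0.439).

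Against GFP cells overexpressing RBM25 differed in few events, no more than regrouped libraries gave. In this comparison 85 of 81568 events passed, 38 lower and 47 higher, and 3534 had an unadjusted p under 0.05. A last exon of ZNF345 was used at 36.7% ± 4.72 in RBM25 cells and 100% ± 0 in GFP cells (n = 2 each), the largest difference (−63.3 points, SE 5.85, adjusted p = 0.0212, limma). NANS, ZNF862 and PIK3C2A fell from 100% to 50% and ZSCAN25 rose from 50% to 100%, each with the same value in both libraries of a group. ZSCAN25 was also at 100% in the sgRNA controls and at 50% in the depleted cells. Cassette exons were lower in 6 events and higher in 13 (exact binomial p = 0.167 over genes). None of 3 BCL2L1 events and none of 24 RBM25 events passed. Logit-transformed PSI left 7 calls, limma on the 4 compared libraries alone 0, and leaving out 1 library gave 1409 to 1524. Summed over the 3 overexpression comparisons the study's groups gave 255 calls and other pairings of the same libraries 192 to 270 (a test chosen after the data were seen), so the calls are not shown to be changes by RBM25.

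Overexpression of the K77R mutant gave a similar number, with 89 of 79656 events against GFP, 43 lower and 46 higher, and 3649 at an unadjusted p under 0.05. ZSCAN25 rose by 50 points and PIK3C2A fell by 50 (n = 2 each, adjusted p = 0.0085 for both, limma), as with RBM25 against the same GFP libraries. Acceptor use of CEP152, a centrosomal protein, and donor use of MTERF1, a mitochondrial factor, fell from 100% to 50%. An acceptor of AC000068.1 was higher by 41.7 points (SE 5.08), at 50% and 66.67% in the GFP libraries and 100% in every other library. As ZSCAN25 was at 100% in the sgRNA controls too, at both events the GFP libraries stood apart from the RBM25, K77R and control libraries. Cassette exons were lower in 9 events and higher in 14 (exact binomial p = 0.405). None of 5 BCL2L1 events and none of 24 RBM25 events passed. Logit-transformed PSI left 1 call, limma on the 4 compared libraries alone 0, and leaving out 1 library gave 1396 to 1495.

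Between K77R and RBM25 cells 81 of 79001 events passed, 46 lower and 35 higher in K77R cells, and 3591 had an unadjusted p under 0.05. This comparison holds the substitution together with any other difference between the cell pools. PARP9 donor use was 25% in both K77R libraries and 100% in both RBM25 libraries (adjusted p = 0.0414, limma). NANS and ZNF862 were at 100% in K77R and 50% in RBM25 cells, and CEP152 and MTERF1 at 50% and 100%. Cassette exons were lower in 8 events and higher in 7 (exact binomial p = 1). None of 13 BCL2L1 events and none of 20 RBM25 events passed. Logit-transformed PSI left 0 calls, with 3826 events at an unadjusted p under 0.05, and limma on the 4 compared libraries alone 0, with 3405. Leaving out 1 library gave 1375 to 1517 calls, of which 29.42% to 68.95% were lower, by the library left out.

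Across exons the differences on adding and on removing RBM25 were nearly unrelated. Over 10792 cassette events they had a Pearson r of −0.04 (jackknife SE 0.0136) and a Spearman rho of −0.0222, and for K77R the values were −0.026 and −0.0361 over 10704 events. These correlations are across events, which are not independent replicates, and the RBM25 overexpression differences themselves correlated at only 0.0418 between library pairs, so r near 0 does not exclude an opposite effect. Without the second RBM25 overexpression library r was −0.0257. The 535 exons that fell on depletion and had a PSI in all libraries averaged 91.71% ± 0.032 in GFP, 92.41% ± 0.141 in RBM25 and 92.13% ± 0.11 in K77R cells (n = 2 each), with mean differences from GFP of 0.701 and 0.42 points and a median of 0 for both. The 18 such exons that rose on depletion had a mean difference of 0.141 points and a median of −0.187 with RBM25, and −1.54 and −2.42 with K77R (percentiles 38.77 and 10.78 of matched sets for the means).

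The effects of RBM25 and K77R against GFP correlated at r = 0.5339 (rho 0.5262, 13249 cassette events), where the GFP libraries are shared. With 1 GFP library for each comparison, so that none was shared, a test chosen after the data were seen, r was −0.0351 and −0.033 for the 2 ways to assign them. Simulated unchanged groups, with the GFP libraries simulated as well, gave r from 0.469 to 0.527 in 50 simulations. The covariance was 15.13 and the simulated covariance 12.15 on average (11.15 to 13.11). The difference between the GFP libraries alone gave 16.66, and that between simulated GFP libraries 12.13. Simulated GFP libraries thus differed less than the real ones, so the simulated range is no firm bound for the observed r. Of the 64755 events tested in both, 49 were called in each comparison and 46 in both, all in the same direction. Simulated groups shared 0.05 calls on average over 20 simulations, and independent lists would share 0.019 higher and 0.0028 lower calls. When the same 6 libraries were regrouped in pairs otherwise, also chosen after the data were seen, 25 to 47 calls were shared by the 2 comparisons against any 1 pair, so 46 did not exceed them.

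**Figure D4:**
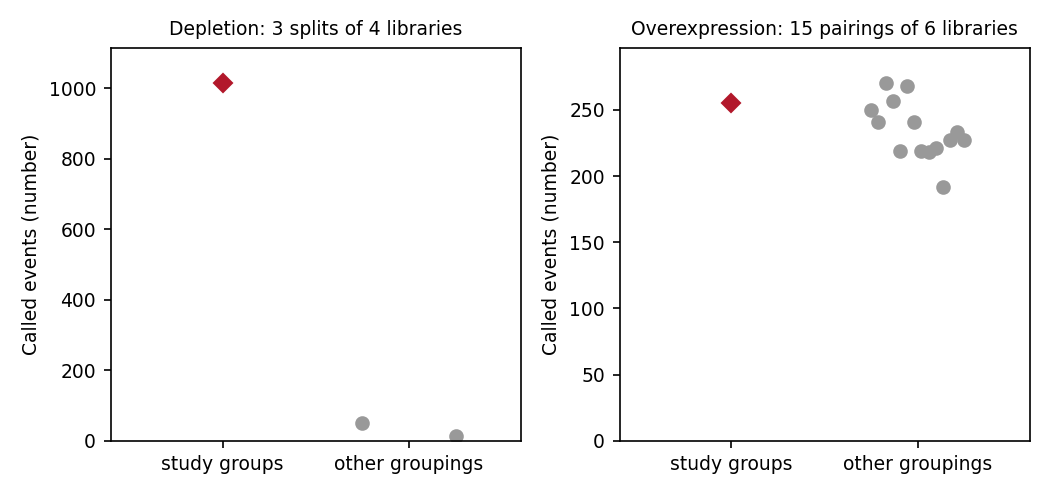
Number of called events (vertical axis) for the study's groups (diamond) and for every other grouping of the same libraries (points), in the depletion experiment (left) and summed over the 3 overexpression comparisons (right). The depletion groups gave 1013 calls and the other 2 splits 50 and 14, while the overexpression groups gave 255 and the other 14 pairings 192 to 270.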

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

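The count of other pairings of the overexpression libraries was chosen as a test after its values had been seen.

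RBM25 and K77R cells differed in 81 events, by limma's direct test of K77R against RBM25. The difference does not involve GFP cells, where PARP9 had no PSI. The 6 with the largest differences were PARP9 (−75 points, K77R minus RBM25), NANS (50), ZNF862 (50), GS1-124K5.11 (−50), CEP152 (−50) and MTERF1 (−50). In each of the 6 both libraries of a group held the same value, among 0, 25, 50 and 100%. A chance origin of such calls stays open: summed over the 3 overexpression comparisons the study's groups gave 255 calls, the highest of the other pairings of the 6 libraries gave 270, and 4 of the 15 pairings, the study's included, gave at least 255. With 15 pairings no share under 0.05 can be reached. A difference between the proteins, which the design names, is not excluded either.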

How the results depend on the processing

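Chosen after seeing the data were the comparison of groups at least 10 points apart without a test, the limits to annotated junctions and to a mean PSI of 20 to 80 (over all or over the overexpression libraries), centring on the mean, gene names as given, a separate GFP library for each comparison and the correlation over all cassette events of the 6 overexpression libraries. Results are given as depletion, RBM25 against GFP, K77R against GFP and K77R against RBM25 (1013, 85, 89 and 81 calls), then depletion cassette exons lower and higher (545 and 20).

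Only the 4 compared libraries, or a replicate block on the library number, left 0 calls in all 6 (2 and 3 residual degrees of freedom in place of 5). Unadjusted p was under 0.05 for 6234, 3343, 3359 and 3405 events with the 4 libraries, and 7774, 3181, 3288 and 3247 with the block. The numbers do not pair the samples (correlations of deviations 0.0206, −0.0139, −0.004 and 0.0272). Without each library in turn calls ran from 1971 to 3548, 1409 to 1524, 1396 to 1495 and 1375 to 1517, with 540 to 1462 lower and 49 to 217 higher cassette exons (540 with 217, 1462 with 49), since a lone library is assumed to vary like the rest. Depletion gave 3548 and 3504 without the first and second depleted library and 1972 and 1971 without the controls, keeping 80.9% to 93.5% of the 1013. The correlation of depletion with RBM25 effects ran from −0.0402 to −0.0257 and that of RBM25 with K77R effects from 0.4312 to 0.7374. The latter reversed to −0.0351 and −0.033 with a separate GFP library for each comparison.

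Logit PSI gave 720 depletion calls, 496 of them shared, and 7, 1 and 0 in overexpression, with 320 lower cassette exons. Without trend and robust options higher cassette exons were 33. A mean PSI of 5 to 95 gave 14, 12 and 10 overexpression calls. At least 20 points gave 591, 30, 30, 24, 330 and 8, and no minimum 1668, 360, 352, 316 and 40 higher cassette exons. By type at 20 points, alternative acceptors were 43, donors 41, first exons 6, cassette exons 338, coordinated cassettes 64, intron retention 47, junction-only acceptors 17 and donors 15, and mutually exclusive 2. Groups 10 points apart without a test numbered 3263, 1124, 1108, 1142, 1332 and 138. Annotated junctions alone gave 158, 4, 4, 4, 58 and 5, and a mean PSI of 20 to 80 gave 179, 7, 6, 2, 85 and 7, from fewer events. With that range set by the overexpression libraries depletion gave 126 calls, 54 lower and 7 higher cassette exons.

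Centring on the mean gave 5126, 3, 3, 4, 332 and 1477. It moves every cassette PSI of the depleted libraries by 6.47 and 6.19 points, subtracted as −6.4713 and −6.1947, exons at 100% included, and 1789 of the 5126 calls had identical deposited values in all 4 libraries. Centring on the median gave 845 depletion calls (690 lower, 155 higher), which included 827 of the 1013.

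No named event reversed. Of the named events' values, 98 lost an adjusted p under 0.05 with the 4 libraries, 98 with the block and 42 on the logit scale. Without each library in turn 29 values of 15 events lost it, an event counting once for each library left out, and 29 others gained it. No list passed by Fisher's test, over genes with at least 2 tested events or with names as given, and lists were not run under the other alternatives. The fit to reads was not run because the table holds none, and unknown depth limits every PSI.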

Other observations

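The tests of intron retention, of the range set by the overexpression libraries and of other splits of the depletion libraries were chosen after their results had been seen; the other tests were written down before, when library means were already known.

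Among cassette exons above 20% in the controls, 2.69% to 4.16% were called lower on depletion. The share called lower was 4.03% of 5857 cassette exons at 100% in both controls, 2.69% of 5159 above 95 to below 100%, 4.16% of 3026 above 80 to 95% and 3.57% of 1203 above 20 to 80%, where 9 exons were called higher. Of 336 exons above 5 to 20% only 1 was called lower and 1 higher, and of 427 at 0 to 5% none was called lower and 4 higher. The 70 retention events that rose on depletion and had a PSI in all libraries averaged 33.7% ± 0.341 in depleted cells and 11.3% ± 0.305 in controls (n = 2 each), with 14.1%, 13.5% and 13.8% in GFP, RBM25 and K77R cells.

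Cassette exons called on depletion were nearly all lower. A lack of room to rise stays open as part of the reason: the share lower was 92.39% at a mean PSI of 20 to 80 over all libraries, a range that the fall itself helps to set, 88.52% with the range set by the overexpression libraries and 82.69% with it set by the controls. Exons in this last range could move both ways, and inclusion was lower in 39 genes and higher in 9. A lack of room is therefore not the whole reason at these exons. Noise from shallower depleted libraries would move exons of intermediate inclusion in either direction, and different exons in each library. The differences of 2 library pairs that share no library correlated at 0.5024 over 4620 cassette events, and at 0.0418 for RBM25 overexpression. These events were chosen by their mean PSI over all libraries, in the range used for centring on the mean. The fall on depletion helps to set that choice too, so the correlation alone cannot exclude such noise, though it lay above the bound set beforehand. Over the 1165 cassette events chosen by the overexpression libraries instead, the depleted libraries averaged 50.995% and 51.443% and the controls 58.67% and 58.918%. This shared fall argues against such noise for these events. Called exons outside that range are not covered by it. The study's grouping gave 1013 calls and the highest other split 50, with 1 of 3 splits as large, too few for a share under 0.05. Loss of RBM25 may underlie the fall, as a hypothesis, and an effect of other differences between the cell pools was not tested.

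Retention calls on depletion were mostly higher. More unspliced or genomic RNA in the depleted libraries could give this if introns rose broadly. Of 7240 annotated introns that differed, 60.26% were higher (95% Wilson interval 59.13 to 61.38), which straddles the bound set at 60, so this stays open.

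If RBM25 acts by dose, exons that fell on depletion might rise when it is added. Over 535 such exons the mean difference from GFP was 0.701 points for RBM25, at percentile 98.07 of random exon sets matched on control PSI (−0.136 to 0.679), and 0.42 points for K77R, at percentile 82.55. This test was first written for the median, and changed to the mean before either was computed, and the median difference was 0 for both. The RBM25 mean passed the bound set beforehand, but its bootstrap interval (0.334 to 1.085) spans that bound, the random sets carry no spread between libraries, the exact p over the 4 libraries was 1 in 3, the smallest possible, and there was no correction for 2 such tests. Both proteins therefore stay undecided, and K77R minus RBM25 (−0.281 points) lay at percentile 12.6, so the proteins were not shown to differ.

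Lower exons were more often a multiple of 3 nt long. Decay of frame-shifted skipped transcripts could hide falls of the other exons. In coding exons with a control PSI of at least 95 the mean change of multiple-of-3 exons minus others was −0.234 points (95% interval −0.494 to 0.039, permutation p = 0.0765), and outside coding sequence 0.34 (−2.652 to 3.318), which leaves this open.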
